A study of Mus musculus with 5 samples.

How the data were processed

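The series holds 5 arrays of mouse CD4+ T cells, 3 of tumor-specific cells activated in the animal and 2 of naive cells. Per the labels' protocols, total RNA was extracted with Trizol, and 6 µg of it was made into biotin-labelled cRNA by the manufacturer's standard protocol. The deposited table gives 1 intensity per probe set and array, on a linear scale, for 45101 probe sets. The scanner software, the summary method and any detection call are not given in the sources used here. The 2% trimmed mean over all probe sets was just under 100 on each array, as a global scaling to that target would leave it. Such a scaling sets the arrays' overall level, so each change is relative to the average probe set.

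Probe sets were named from the platform annotation supplied with the table. Of them 34945 had 1 gene symbol, 932 had several, 9160 had none and 64 were array controls. The Entrez ID of 34754 of the first kind was in a RefSeq gene table of assembly GRCm38.p6, used for names only. In the gene comparison no gene was named from a probe set with several symbols. For each of 18193 genes, 1 probe set was used, that with the highest mean log2 value over the 5 arrays among those with 1 symbol. Among the 81 genes chosen for naming, 35 had more than 1 probe set above the filter, and 3 of these (Ahr, Cox8a and Il2ra) had a probe set in the opposite direction.

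Intensities were transformed as log2(intensity + 16). Array medians on this scale differed by less than the 0.5 set as the limit for an added quantile step, so none was applied. A gene was tested if its probe set lay above the 40th percentile of its array on at least 2 of the 5 arrays, which left 12873 genes. The model was limma's lmFit with the group as its only term and eBayes with an intensity trend (R 4.3.3, limma 3.58.1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are those of the moderated test. Fold changes are on the scale of log2(intensity + 16).

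Gene lists were tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over 33 lists with at least 3 tested members. The lists were 25 gene lists (cell division, activation, helper subsets, cytokines and receptors, trafficking, cytotoxicity, transcription factors, interferon responses, metabolism, ribosomal proteins and stress) and 9 lists of markers of other cell types. Of 838 list entries, 82 have no probe set with 1 gene symbol in the annotation used and were not analysed here. Camera with an estimated correlation and fry were alternatives. With an estimated correlation, camera also lowers the degrees of freedom of its test to the residual ones, 3 here. The lists, the tests, the filter and the rule for named genes were fixed before the data were examined. That rule took the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, leaving out symbols of predicted or unnamed genes, a fixed panel of T cell genes whatever their result, and in each gene list the 2 largest rises and 2 largest falls among called members. Other names in the text were chosen after their values were seen.

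The labels call each sample a biological replicate from an independent experiment. No pair of arrays was a copy: at most 0.947% of values were equal between any pair. Pearson correlations across tested genes, which are not independent replicates, ran from 0.970 to 0.977 within groups and from 0.929 to 0.944 between groups. The first principal component held 57.7% of the variance and separated the groups. The second held 18.7% and ordered the arrays by the intensity of the bioC hybridisation control, with activated replicate 2 in between, at -1.06. A split of the arrays by bioC, found in the data and not given by the labels, was fitted as a block. It was an alternative chosen after seeing the data, and values on each side of it were computed. Whether it is a batch of hybridisation is not known from the sources used here.

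The alternatives were quantile normalization, median centring, no filter, a filter at the 60th percentile, pseudocounts of 1 and 64, the mean of all probe sets of a gene, probe sets without a shared-sequence suffix only, eBayes without the trend and with robust variances, array weights, the replicate number as a block, and leaving out each array in turn. The test code was tested on simulated arrays with the real genes' means and spreads, with 200 of 12873 genes changed between activated and naive in each of 5 runs. It recovered 66.2% of genes changed by 1 on the log2 scale and 98.4% of those changed by 2, and 7.63% of its calls were false, which is above the threshold of 0.05. The simulated noise was independent between genes and held no bioC split. In the data 1352 genes were called, a larger share than was changed in the simulation. These rates therefore need not hold for the data.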

Results

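Gene expression was measured on 5 Affymetrix arrays in mouse CD4+ T cells that carry a transgenic T cell receptor specific for the MOPC315 myeloma, a plasma cell tumor of BALB/c mice. The 3 activated samples came from the lymph nodes draining a subcutaneous tumor inoculum of 100000 cells in 250 µl of Matrigel, taken on day 8, with the nodes of 12 to 15 mice pooled per experiment. These cells were sorted as CD4+ and positive for GB113, an antibody staining named in the labels, at a purity of at least 95%. The 2 naive samples came from pooled lymph nodes of uninjected mice of the same transgenic kind on a SCID background, which lacks other T and B cells. No sort purity was available here for the naive samples. A difference in sorting, if there was any, would go with the groups. Each sample was an independent experiment on pooled mice. The values were probe set intensities on a linear scale. The number of arrays, 3 against 2, limits the precision of every comparison. No group injected with Matrigel alone was analysed here.

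The comparison asks which transcripts differ between tumor-specific T cells activated in the animal and their naive counterparts, which the series title describes as a profiling of Th1 cells. Activated cells had more of the inhibitory receptor Ctla4, the costimulatory receptor Tnfrsf9, the proliferation marker Mki67 and the antigen receptor-induced nuclear receptor Nr4a1. They had less of the insulin-like growth factor binding protein Igfbp4, the nucleotidyl transferase Dntt and the interferon-induced genes Oas2 and Ifit1. Among 12873 genes tested, 819 were higher and 533 lower in activated cells at an adjusted p under 0.05 in limma's moderated test with Benjamini-Hochberg adjustment. Of these, 490 were higher and 224 lower by at least 2-fold. Of all tested genes, 40.9% had the 3 activated arrays on 1 side of both naive arrays, against the 20% that chance gives. The calls were fewer when 1 array was left out: 520 higher and 276 lower without activated replicate 2, 541 and 334 without naive replicate 1, and 462 and 181 without naive replicate 2. Without activated replicate 1, which had more transcripts on the lists of other cell types described further on, 677 genes were higher and 382 lower.

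Ctla4 rose from an intensity of 9.0 ± 6.22 (SD, n = 2) in naive cells to 632 ± 184 (SD, n = 3) in activated cells. On the scale of log2(intensity + 16), which understates changes of dim genes, this was a log2 fold change of 4.67 ± 0.26 (SE, adjusted p = 6.0e-06), the largest among the called genes on that scale. For the 5 called named genes whose naive arrays all lay below the filter intensity (Tnfrsf9, Dusp4, Ube2c, Tk1 and Csf2), and for other genes with dim naive values such as Ctla4, the size of the rise is set in part by the pseudocount, and their order has no meaning. Tnfrsf9 rose by 4.51, Lad1, an anchoring filament protein of epithelia, by 3.94, and Mki67 by 3.93. Nr4a1 rose by 3.91, and Ikzf2, the transcription factor Helios, rose by 3.82, to an intensity of 2170 ± 186 (SD, n = 3) against 143 ± 57.6 (SD, n = 2). Ube2c, a ubiquitin-conjugating enzyme of mitosis, rose by 3.72, the ribonucleotide reductase subunit Rrm2 by 3.70, the MAP kinase phosphatase Dusp4 by 3.68 and the folate receptor 4 gene Izumo1r by 3.54. On the same scale the largest fall was that of the cytoskeletal adaptor Pdlim4, with a log2 fold change of -4.10 ± 0.33 (SE, adjusted p = 3.4e-05). Igfbp4 fell by 3.61, from 3755 ± 358 (SD, n = 2) to 301 ± 88.7 (SD, n = 3). The gut-homing receptor Ccr9 fell by 2.72 on a probe set with a shared-sequence suffix. Dntt fell by 3.35, the motor protein Myo6 by 3.09, the receptor Treml2 by 3.03, the 2'-5' oligoadenylate synthetase Oas2 by 2.83, Ifit1 by 2.62, Plac8 by 2.54 and the complement regulator Cd55 by 2.51. The call of Ccr9 was lost on probe sets without such a suffix, where its log2 fold change was -0.77, with robust variances, at an unchanged -2.72, and without naive replicate 2, at -2.51. Averaging all probe sets of a gene gave smaller log2 fold changes for Tnfrsf9, at 2.79, Myo6, at -1.88, Treml2, at -1.62, and Ccr9, at -1.33, and these 4 passed the test.

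**Figure D1:**
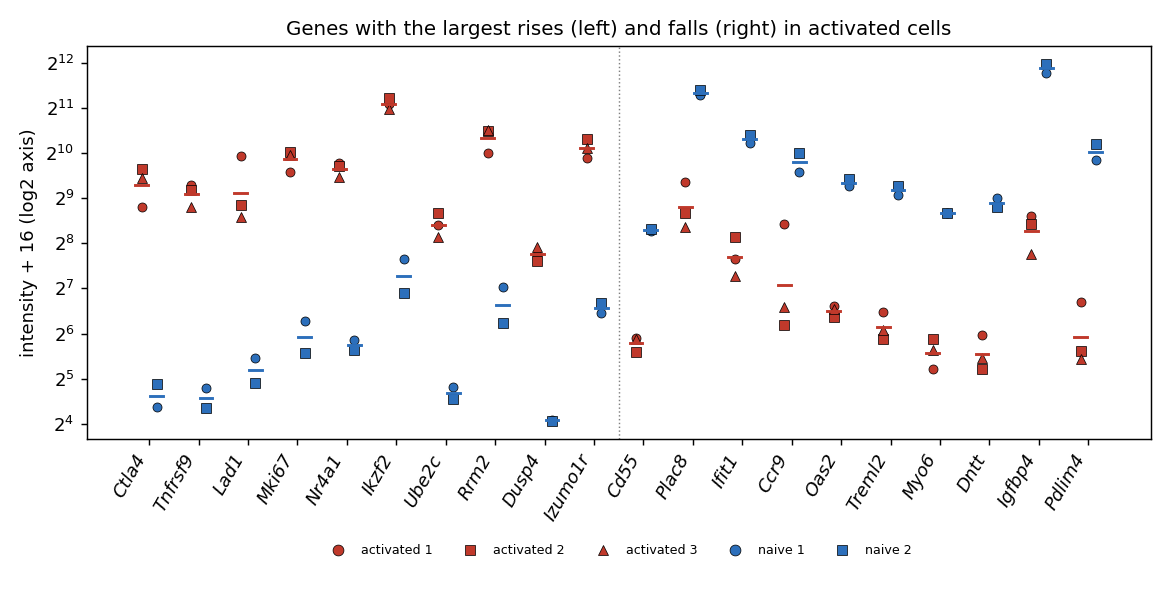
Intensity plus 16 on a log2 axis for the 10 called genes with the largest rises and the 10 with the largest falls, with 1 point per array (red, activated; blue, naive; marker shape, replicate) and a bar at each group's mean on the log2 scale. For Ctla4 the activated arrays lie at intensities from 427.9 to 784.7 and the naive arrays at 4.6 and 13.4.

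Genes of cell division rose together. Of 34 tested members of the mitosis list, 32 rose and 0 fell, with a median log2 fold change of 2.53, and the same 32 to 0 resulted when adjusted over the list alone. Ube2c and Mki67 were among them. Of 34 tested members of the DNA replication and S phase list, 30 rose and 0 fell, or 32 and 0 adjusted over the list alone, with a median of 1.32. Rrm2 was among them. So was the thymidine kinase Tk1, which rose to an intensity of 162 ± 13.0 (SD, n = 3) from naive arrays below the filter. The log2 fold change of Tk1, at 3.26, was 5.62 with a pseudocount of 1 and 1.76 with 64. In camera, limma's competitive list test with a preset correlation, both lists were higher (adjusted p = 1.0e-44 for mitosis and 1.1e-29 for replication). With a correlation estimated from the data, replication kept its call (adjusted p = 0.037) and was the only list of 33 to do so; mitosis had an adjusted p of 0.088.

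Activation markers and genes associated with follicular helper cells, regulatory T cells and coinhibition were also higher. These lists share members, such as Icos, Tnfrsf18, Pdcd1 and Ctla4, so their counts and tests are not independent of each other. Of 24 tested activation markers, 14 rose and 0 fell over all genes and adjusted over the list alone, Tnfrsf9 and Nr4a1 among them. The list was higher in camera (adjusted p = 2.2e-11, and 0.082 with an estimated correlation). The adhesion receptor Cd44 rose by 1.15, a call that was lost with no filter, without the intensity trend, and without activated replicate 1, activated replicate 2 or naive replicate 2, where its log2 fold change was 1.05, 1.12 and 0.60. The interleukin 2 receptor chain Il2ra had a log2 fold change of -0.24 (adjusted p = 0.58), and its 2 probe sets lay at -0.24 and 0.10. In the TFH list, 10 of 13 tested members rose and 0 fell, also adjusted over the list alone (camera adjusted p = 1.7e-11; adjusted p = 0.10 with an estimated correlation). The B cell follicle homing receptor Cxcr5 rose by 3.47, from 32.2 ± 7.99 (SD, n = 2) to 519 ± 81.8 (SD, n = 3). The costimulator Icos rose by 2.83, the surface glycoprotein Cd200 by 2.43, the repressor Bcl6 by 1.85 and the inhibitory receptor Pdcd1 by 1.39. In the TREG list, 7 of 13 tested members rose and 1 fell, or 8 and 2 adjusted over the list alone (camera adjusted p = 4.0e-05; adjusted p = 0.088 with an estimated correlation). Ctla4, Ikzf2 and Izumo1r were among the 7, and the integrin Itgae fell by 1.87. Foxp3, the lineage factor of regulatory T cells, had intensities of 12.5 ± 6.25 (SD, n = 3) in activated and 12.1 ± 6.93 (SD, n = 2) in naive cells, with a log2 fold change of 0.02 ± 0.30 (SE, adjusted p = 0.98) whose sign turned with quantile normalization and without naive replicate 1. Of 14 tested coinhibitory receptors and ligands, 7 rose and 1 fell, or 8 and 2 adjusted over the list alone (camera adjusted p = 1.1e-04; adjusted p = 0.088 with an estimated correlation), and the faller was Vsir, which encodes the inhibitory ligand VISTA.

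Genes of the TH1 list changed in both directions. Of 25 tested members, 8 rose and 2 fell, or 12 and 3 adjusted over the list alone, and the list was higher in camera (adjusted p = 2.1e-04), with an adjusted p of 0.36 with an estimated correlation. The TH1 cytokine Ifng rose by 2.37 ± 0.39 (SE, adjusted p = 0.0031), from 17.9 ± 6.51 (SD, n = 2) to 179 ± 119 (SD, n = 3). Its lineage factor Tbx21 rose by 1.35, the death ligand Fasl by 1.36 and the transcription factor Bhlhe40 by 2.62. The interleukin 18 receptor chain Il18r1 fell by 2.15 and the selectin ligand Selplg by 0.79, a call that Selplg lost without naive replicate 1, at -0.68. Il2, Tnf, Cxcr3 and Il12rb2 did not pass the test, with log2 fold changes of 0.75, 0.94, 0.92 and 0.71 and adjusted p of 0.12, 0.13, 0.11 and 0.19. Il2 and Il12rb2 were dim, with mean intensities of 24.4 and 13.9 in activated and 8.1 and 1.85 in naive cells. The filter intensity ran from 10.5 to 13.4 among the arrays. At such levels the pseudocount shrinks changes, so these 2 results do not show that the genes were unchanged. Tnf passed without naive replicate 2, at 1.64, and Cxcr3 passed without naive replicate 1, at 1.63, and with the replicate number as a block, at 0.93. Of 7 tested TH2 genes only Maf rose, by 1.15, and 0 fell, or 1 and 2 adjusted over the list alone (camera adjusted p = 0.57). The call of Maf was lost when all its probe sets were averaged, at 0.37, and without naive replicate 2, at 0.94. The TH2 factor Gata3 had a log2 fold change of -0.49 (adjusted p = 0.25). Il4, Il17a and Il10 were not above the intensity filter on at least 2 arrays and were not tested. Of 8 tested TH17 genes, 2 rose and 0 fell, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.0014; adjusted p = 0.30 with an estimated correlation). They were Batf, at 1.91, a factor used in several helper subsets, and the aryl hydrocarbon receptor Ahr, at 0.98, whose second probe set above the filter lay at -0.26. The TH17 list had a median of 0.58, against 0.38 without activated replicate 2, and lost its call with averaged probe sets, at 0.33. Ahr lost its call without the filter, with averaged probe sets, at 0.36, and without activated replicate 2 or 3 or naive replicate 1 or 2, at 0.79, 1.04, 1.17 and 0.78.

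Of 30 tested cytokines, 11 rose and 2 fell, or 15 and 2 adjusted over the list alone (camera adjusted p = 9.9e-06; adjusted p = 0.24 with an estimated correlation). The growth factor Csf2 rose to an intensity of 73.5 ± 45.5 (SD, n = 3) from naive arrays below the filter. Its log2 fold change of 2.15 was 4.25 with a pseudocount of 1 and 0.997 with 64. The 2 that fell were Tnfsf10, described with the cytotoxic genes, and the interleukin 6 family cytokine Osm, at -0.84. Osm lost its call without the filter and without activated replicate 1, activated replicate 3 or naive replicate 2, at -0.80, -0.76 and -0.67. Of 33 tested effector transcription factors, 14 rose and 4 fell, or 17 and 7 adjusted over the list alone (camera adjusted p = 2.3e-04; adjusted p = 0.26 with an estimated correlation). Bhlhe40 and Irf4 were among the rises, at 2.62 and 2.49 (Irf4 1.56 with averaged probe sets), and Jun and Prdm1 among the falls, at -2.19 and -1.11. Prdm1, which encodes Blimp-1, lost its call without the filter and without activated replicate 2, naive replicate 1 or naive replicate 2, at -1.06, -0.99 and -1.23. Of 20 tested cytotoxic effector genes, 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.019; adjusted p = 0.58 with an estimated correlation). The protease inhibitor Serpinb6b rose by 2.38, the receptor Klrk1 by 1.72, and the ligand Tnfsf10 fell by 0.69, a call it lost on leaving out any array, with log2 fold changes from -0.73 to -0.65, and on all arrays without the filter, without the trend and with the replicate number as a block. The list lost its call without activated replicate 1, with a median of 0.25 against 0.28 on all arrays, and without naive replicate 2, at 0.23; without naive replicate 1 the median was 0.42. The granzyme Gzmb had intensities of 751, 209.7 and 68.7 on the activated arrays and 86.7 and 23.0 on the naive arrays (adjusted p = 0.13). It passed without activated replicate 3 and with the replicate number as a block, at 2.72 in both, which give activated replicate 1 more weight, and with the bioC split described further on as a block, at 1.63. Without activated replicate 1 the log2 fold change of Gzmb was 1.13. On activated replicate 1 NK cell genes were also higher, with a median log2 difference of 1.61 from the mean of replicates 2 and 3.

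Interferon-response genes were lower in activated cells. Of 29 tested members of the type I interferon list, 0 rose and 22 fell, or 2 and 24 adjusted over the list alone, with a median log2 fold change of -1.02. Camera placed the list lower (adjusted p = 5.3e-19), and the adjusted p was 0.085 with an estimated correlation. Oas2 had intensities of 81.3, 66.0 and 77.8 on the activated arrays and 595.9 and 668.8 on the naive arrays. Ifit1, which binds viral RNA, fell from 1255 ± 110 (SD, n = 2) to 197 ± 65.5 (SD, n = 3). Of 27 tested members of the interferon gamma list, 0 rose and 12 fell, or 0 and 16 adjusted over the list alone, with a median of -0.67 (camera adjusted p = 6.7e-10; adjusted p = 0.082 with an estimated correlation). The cytokine signalling suppressor Socs3 fell by 2.41 and the guanylate-binding protein Gbp7 by 1.76.

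Of 27 tested naive and quiescence genes, 10 fell and 3 rose, or 11 and 5 adjusted over the list alone (camera adjusted p = 0.0010; adjusted p = 0.097 with an estimated correlation). The median was -0.23, and -0.40 without naive replicate 2. Igfbp4 and Treml2 led the falls. The interleukin 7 receptor Il7r fell by 1.98, from 1306 ± 179 (SD, n = 2) to 325 ± 85.2 (SD, n = 3), and the egress receptor S1pr1 fell by 1.18. The 3 that rose were the endosomal protein Nsg2, at 1.09, the cannabinoid receptor Cnr2, at 0.88, and the adhesion molecule Pecam1, at 0.82; Cnr2 lost its call without the filter, without the trend, with the replicate number as a block, at 0.73, and without activated replicate 2 or 3 or naive replicate 1 or 2, at 0.87, 0.73, 0.83 and 0.94. The lymph node homing receptor Ccr7 had intensities of 1500 ± 66.2 (SD, n = 3) and 1592 ± 53.3 (SD, n = 2), with a log2 fold change of -0.09 (adjusted p = 0.78). Of 18 tested T cell identity genes, 5 rose and 1 fell, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.0013; adjusted p = 0.10 with an estimated correlation). The median was 0.44, or 0.23 with averaged probe sets. Cd5, a negative regulator of receptor signalling, rose by 1.85, the related Cd6 by 1.46, and Thy1 fell by 0.79. Thy1 lost its call without the trend and without activated replicate 2, naive replicate 1 or naive replicate 2, at -0.86, -0.86 and -0.72. Cd4 had intensities of 1028 ± 104 (SD, n = 3) and 755 ± 32.2 (SD, n = 2) and did not pass (adjusted p = 0.12), although it did when its 2 probe sets, at 0.43 and 1.31, were averaged and with the replicate number as a block, at 0.51.

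Lists of receptors and trafficking genes did not pass as a whole. Of 29 tested adhesion and trafficking genes, 7 rose and 7 fell, or 9 and 8 adjusted over the list alone (camera adjusted p = 0.74). The membrane-binding protein Anxa2 rose by 1.99 and the galectin Lgals1 by 1.34; Anxa2 lay at 0.81 with averaged probe sets and lost its call without naive replicate 2, at 1.41. Of 32 tested cytokine receptors, 4 rose and 4 fell, or 4 and 5 adjusted over the list alone (camera adjusted p = 0.74), with a median of -0.02 and a mean of 0.03. The interleukin 2 and 15 receptor chain Il2rb rose by 2.43 and the decoy receptor Il1r2 by 1.51. Of 13 tested chemokine receptors, 2 rose and 1 fell, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.14): Cxcr5, Cxcr4, at 1.24, and Ccr9. This list passed camera without naive replicate 1, with a median of 1.001 against 0.36, and with the replicate number as a block, at 0.65; without activated replicate 1 the median was 0.01. Of 23 tested chemokines, 0 passed limma's test in either direction, also adjusted over the list alone, with 1 higher and 0 lower at an unadjusted p under 0.05 (camera adjusted p = 0.56, fry adjusted p = 0.80). The chemokine list passed camera without activated replicate 2, with a median of 0.20 against 0.05.

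Metabolic lists shifted upward by smaller amounts. Of 19 tested glycolysis genes, 7 rose and 1 fell, also adjusted over the list alone, with a median log2 fold change of 0.46 (camera adjusted p = 2.1e-04; adjusted p = 0.088 with an estimated correlation). The hexokinase Hk2 rose by 2.26, from 10.5 ± 2.12 (SD, n = 2) to 111 ± 14.0 (SD, n = 3), and the isomerase Tpi1 rose from 132 ± 18.5 (SD, n = 2) to 405 ± 45.4 (SD, n = 3). Pdk1, which restrains pyruvate oxidation, fell by 1.66, a call that was lost without naive replicate 2, at -1.42. Of 20 tested cholesterol synthesis genes, 6 rose and 0 fell, or 9 and 0 adjusted over the list alone, with a median of 0.46 (camera adjusted p = 1.2e-06; adjusted p = 0.088 with an estimated correlation), led by Cyp51, at 1.35, or 0.81 with averaged probe sets, and Idi1, at 1.34. Of 32 tested oxidative phosphorylation genes, 1 rose and 0 fell, also adjusted over the list alone, with a median of 0.30 (camera adjusted p = 1.2e-04; adjusted p = 0.36 with an estimated correlation). The 1 was the cytochrome oxidase subunit Cox8a, at 0.84, with a probe set at -0.20, a value of 0.54 with averaged probe sets and a call lost without activated replicate 2 or naive replicate 2, at 0.78 and 0.77. Of 23 tested ribosomal protein genes, 0 passed limma's test in either direction, also adjusted over the list alone, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.19, fry adjusted p = 0.53). Their median of -0.11 turned to 0.0076 with quantile normalization, and the list passed camera without activated replicate 1, at -0.19.

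**Figure D2:**
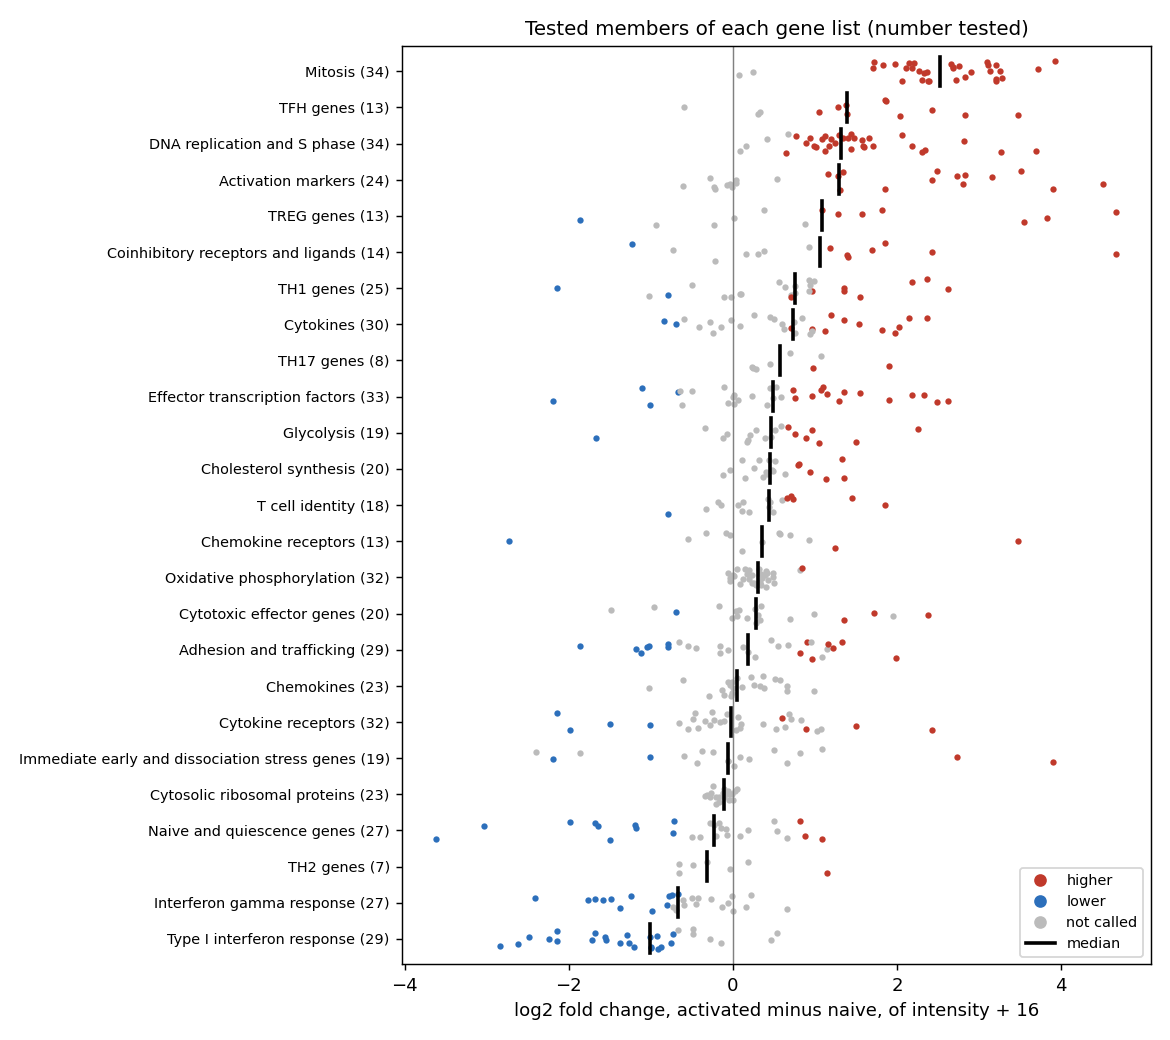
Log2 fold change, activated minus naive, of intensity plus 16 for the tested members of the 25 gene lists, with 1 point per gene (red, higher; blue, lower; grey, not past the test), a black bar at each list's median and the number tested in brackets. The median is highest for mitosis, at 2.53, and lowest for the type I interferon response, at -1.02.

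Transcripts on the lists of other cell types were uneven among the activated arrays. The median log2 difference of activated replicate 1 from the mean of replicates 2 and 3 was 1.61 for NK, 1.28 for dendritic cell, 0.55 for granulocyte and 0.37 for macrophage genes. Of the 17 macrophage genes, 6 were highest on activated replicate 1, and their median intensity was 40.9 there and 59.8 on activated replicate 3. Activated replicate 1 had the macrophage lysozyme Lyz2 at an intensity of 1953.9, against 35.8 and 353.6 on activated replicates 2 and 3 and 118.2 and 60.3 on the naive arrays. The class II chain H2-Aa lay at 1174.6, 32.0 and 104.0 on activated replicates 1, 2 and 3, and at 99.9 and 26.8 on the naive arrays. The natural killer receptor Ncr1 lay at 265.3, 9.9 and 5.9, and at 5.6 and 11.2. The dendritic cell list was higher in camera (adjusted p = 0.0013; adjusted p = 0.53 with an estimated correlation), with a median of 1.07 on all arrays and 0.45 without activated replicate 1. Of its 14 tested members 1 rose and 0 fell, also adjusted over the list alone: Cd83, which activated lymphocytes also carry, at 3.09. Of 12 tested NK cell genes, 2 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.14). These were Eomes, at 2.19, a factor that effector T cells also use, and the inhibitory receptor Klrc1, at 2.21. On activated replicates 1, 2 and 3 Eomes lay at 696.4, 281.6 and 440.9. The NK list passed camera without activated replicate 2, with a median of 1.02, and without activated replicate 3, with 1.10, against 0.86 on all arrays and 0.06 without activated replicate 1. It also passed on probe sets without a shared-sequence suffix, at 0.98, and with the replicate number as a block, at 1.10.

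Of 17 tested macrophage genes and 7 neutrophil and granulocyte genes, 0 passed limma's test in either direction, also adjusted over the list alone (camera adjusted p = 0.11 and 0.47, fry adjusted p = 0.61 for both). At an unadjusted p under 0.05, 1 macrophage gene was higher and 0 granulocyte genes differed. The macrophage list passed camera without activated replicate 2, with a median of 1.14 against 0.45. Of 11 tested B cell genes, the inhibitory receptor Cd22 rose by 1.21 and the immunoglobulin heavy chain gene Ighm fell by 1.72, or 1 rise and 2 falls adjusted over the list alone (camera adjusted p = 0.57). Of 13 tested plasma cell and plasmacytoma genes, Irf4 and Derl3 rose and Prdm1 fell, or 3 rises and 2 falls adjusted over the list alone (camera adjusted p = 0.37). The 2 CD8 genes were too few for the list test; Cd8b1 fell by 1.61 and Cd8a had a log2 fold change of -0.35, with 0 rises and 1 fall also adjusted over the list alone. Of 7 tested red cell and platelet genes, 0 passed limma's test in either direction, also adjusted over the list alone, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.89, fry adjusted p = 0.65). Of 13 tested stromal and endothelial genes 1 rose and 0 fell, also adjusted over the list alone: Pecam1 (camera adjusted p = 0.47). Of 19 tested immediate early and dissociation stress genes, Nr4a1 and Egr1 rose by 3.91 and 2.73, and Jun and Klf6 fell by 2.19 and 1.01, or 4 rises and 2 falls adjusted over the list alone (camera adjusted p = 0.79). The median of this list was -0.05 and its mean 0.04. The heat shock gene Hspa1b lay at 2752.8 on naive replicate 2, against 150.4 on naive replicate 1 and 117.5, 33.3 and 305.2 on the activated arrays.

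A hybridisation control, bioC, split the arrays across the groups. The mean intensity of the bioC control probe sets was 169 on activated replicate 3 and 207 on naive replicate 2, against 714, 634 and 716 on activated replicates 1 and 2 and naive replicate 1. The bioB control was also lowest on these 2 arrays, at 152 and 194 against 232, 215 and 273 on the others. The second principal component lay at -22.6 and -16.2 on them and at 19.6, -1.06 and 20.3 on the others. No date of hybridisation was used here. With this split as a block, fitted after seeing the data, 1089 genes were higher and 859 lower, and 494 were higher and 236 lower by at least 2-fold. All 19 lists called in camera kept their call with the block and the sign of their median on both sides of the split, and the ribosomal list was then lower as well (adjusted p = 0.021). All 1352 called genes have groups that do not overlap, which fixes their sign on both sides of the split. The side with high bioC, activated replicates 1 and 2 against naive replicate 1, and the side with low bioC, activated replicate 3 against naive replicate 2, gave median log2 fold changes of 2.47 and 2.75 for mitosis, 1.33 and 1.28 for DNA replication and 1.22 and 1.34 for activation markers. In the same order they were 1.29 and 1.90 for TFH genes, 1.10 and 1.06 for TREG genes, 0.54 and 0.74 for TH1 genes, 0.58 and 0.67 for cytokines, -1.05 and -1.13 for the type I interferon list and -0.50 and -0.79 for the interferon gamma list. They were 0.56 and 0.42 for glycolysis, 0.35 and 0.52 for cholesterol synthesis, 0.40 and 0.15 for oxidative phosphorylation, -0.31 and -0.18 for naive and quiescence genes, and 1.14 and 0.60 for dendritic cells. They were 0.90 and 0.88 for coinhibitory genes, 0.56 and 0.56 for TH17 genes, 0.50 and 0.49 for effector transcription factors, 0.32 and 0.29 for cytotoxic genes, and 0.41 and 0.39 for T cell identity genes. The 3'/5' log2 difference of the actin control probe sets was 0.83 on naive replicate 2, 0.50 on naive replicate 1 and 0.25, 0.37 and 0.32 on the activated arrays.

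**Figure D3:**
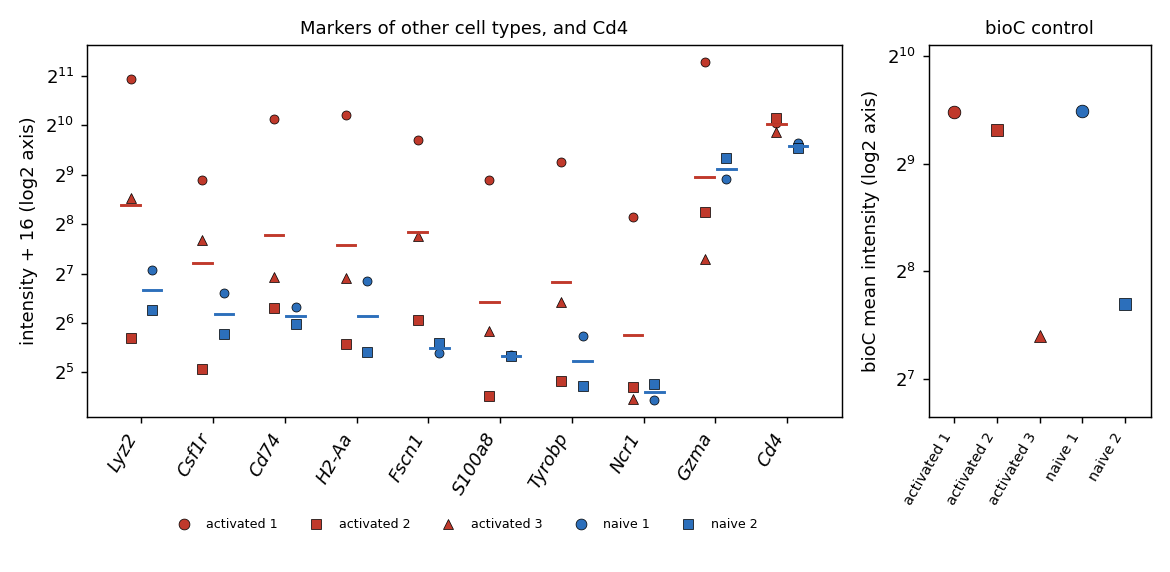
Left, intensity plus 16 on a log2 axis for markers of macrophages (Lyz2, Csf1r), dendritic cells (Cd74, H2-Aa, Fscn1), granulocytes (S100a8) and NK cells (Tyrobp, Ncr1, Gzma) and for Cd4, with 1 point per array and a bar at each group's mean on the log2 scale; the 9 markers were chosen after their values were seen. Right, mean bioC control intensity per array, which is 169 on activated replicate 3, 207 on naive replicate 2 and at least 634 on the others.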

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

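Probe sets outside the gene-level comparison also differed between the groups. Of 5518 tested probe sets with no gene symbol or with several, 104 were higher and 135 lower in activated cells by the same limma test. The largest rise among them was a log2 fold change of 3.996, on a probe set with no gene symbol. Probe sets shared by H2ac histone genes, by Bcl2a1 genes and by Tyms and Tyms-ps rose by 3.16, 2.88 and 2.70. The largest fall was -2.55, on a probe set shared by Cela3a and Cela3b. A probe set shared by Amy2a genes lay at -2.27. The Cela3 and Amy2a genes encode pancreatic enzymes, and whether the naive samples held RNA of other tissue was not tested. A probe set shared by the T cell receptor genes Trgv4 and Trgv2 lay at -2.02. The probe sets are listed here because they carry a signal in data that the gene comparison does not use, and no explanation was tested.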

How the results depend on the processing

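The block by the bioC control was chosen after seeing the data. Of 68 called named genes, 55 kept their call and 0 changed sign in every alternative in which they were tested, and 59 kept it in every alternative that used all arrays. Of the 10 tested named genes that were not called, 4 passed in at least 1 alternative. The list counts stayed within 1.5 times with every normalization, filter, pseudocount, probe set rule and left-out array tried. The robust variances do not enter camera. With an estimated correlation the lists called were 1 higher and 0 lower, against 16 and 3, and with fry, where the TH1, TH17, cytotoxic, oxidative phosphorylation and dendritic cell lists lost their calls, 11 and 3. The estimate was 0.43 for mitosis, but 0.0039 for interferon gamma and -0.016 for T cell identity genes, below the preset 0.01. A high correlation therefore does not account for every lost call. That setting also left camera 3 residual degrees of freedom. Genes lower in activated cells numbered 349 with no filter, where more genes are tested, and 859 with the bioC block, against 533. With a pseudocount of 64, which shrinks the changes of dim genes by construction, 248 genes were higher and 116 lower by at least 2-fold, against 490 and 224. Of the called named genes, 15 and 5 list medians were smaller by over 1.5 times with that pseudocount, 3 genes and 2 list medians larger with a pseudocount of 1, and 10 genes and 2 list medians smaller with averaged probe sets. Without the filter the medians of TH17 genes (0.37 against 0.58) and cytokines (0.43 against 0.73) were smaller, and with the 60th percentile filter that of dendritic cell genes was larger (1.64 against 1.07). On probe sets without a shared-sequence suffix the dendritic cell median was 0.69 and that of naive and quiescence genes -0.39, against -0.23. Leaving out 1 array gave 462 to 704 genes higher and 181 to 494 lower, with fewer samples; where 1 naive array remained, it was assumed to vary like the activated ones. The replicate number as a block gave 974 genes higher and 796 lower. That block takes activated replicate 3, which has no naive array of its number, out of the comparison, so the fold changes of named genes are those without this array. The samples were treated as unpaired. The deviations of same-numbered arrays from their group means correlated across genes, which are not independent replicates, at 0.17 for number 1 and -0.13 for number 2, and with 2 naive arrays this decides little. Signs turned only for values near 0, and the cause was not tested. With quantile normalization these were Foxp3 (-0.0026) and the medians of ribosomal proteins (0.0076) and immediate early genes (0.0034). Without the filter they were the plasma cell (-0.0042) and red cell (0.0098) medians. The 60th percentile filter turned the chemokine median (-0.010), the pseudocount of 64 the red cell median (0.029), array weights the plasma cell median (-0.041), and the replicate block the chemokine (-0.061) and red cell (0.010) medians. Leaving out 1 array, Foxp3 ranged from -0.24 to 0.17, and the medians from -0.15 to 0.39 for chemokines, -0.12 to 0.11 for red cells, -0.16 to 0.031 for cytokine receptors and -0.039 to 0.34 for stromal genes. Values of dim genes are limited as well, since no detection calls or background values were used here.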

Other observations

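All lists and tests in this part were chosen after the group comparison was seen; the values of the list members used to test the thymocyte and anergy hypotheses had not been looked at. Among regulators of receptor signalling, 7 of 18 tested genes on a list of MAP kinase phosphatases, RGS, Sprouty and Spred genes and Ras GTPase-activating genes rose and 0 fell (camera adjusted p = 2.1e-04 over 6 added lists; adjusted p = 0.084 with an estimated correlation). Besides Dusp4, they included Rgs16, at 1.67, Rgs10, at 1.59, Rasal1, a Ras GTPase-activating gene, at 1.46, and Dusp6, a phosphatase of ERK, at 1.33, and no Sprouty or Spred gene. Of 18 tested TNF receptor family genes, 5 rose and 0 fell (adjusted p = 0.020; adjusted p = 0.28 with an estimated correlation), with a median of 0.06, 10 positive and 8 negative log2 fold changes. Tnfrsf4, Tnfrsf9 and Tnfrsf18 are also on the activation marker list; another was Tnfrsf19, from 33.2 ± 14.1 (SD, n = 2) to 458 ± 69.8 (SD, n = 3), a log2 fold change of 3.29. Of 21 tested genes of DNA methylation and Polycomb, 5 rose and 1 fell (adjusted p = 8.4e-04; adjusted p = 0.084 with an estimated correlation). Uhrf1, which is also on the DNA replication and S phase list, rose by 2.30. The helicase Hells rose by 2.11, the histone methyltransferase Ezh2 by 1.97 and the DNA methyltransferase Dnmt3a by 1.15, and Cbx7 fell by 1.01. Of 19 tested apoptosis regulators, Pmaip1 and Bad rose and Bcl2 and Cflar fell, at 1.04, 0.79, -0.97 and -0.76, and the list did not pass (adjusted p = 0.084). The other 15 were not called. A probe set shared by the Bcl2-related genes Bcl2a1a, Bcl2a1b and Bcl2a1d, left out of the list test for its several symbols, rose by 2.88. The list is therefore not a full account of such genes.

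The macrophage, dendritic cell, granulocyte and NK lists had 50 tested members. Of these, 22 were over 1 log2 higher on activated replicate 1 than the mean of replicates 2 and 3. Among all tested genes 1.35% were. The median log2 difference of activated replicate 1 from that mean was 0.84 over the 50 members. Over 44 members of the B cell, plasma cell, red cell and stromal lists it was 0.07, so the lists differed by 0.77, with medians of 1.61 for NK, 1.28 for dendritic cell, 0.55 for granulocyte and 0.37 for macrophage members; these 4 lists were picked for their values on this array, so the difference describes the pattern and does not test its source. After quantile normalization the 4 lists' median was 0.79. The array medians already lay at 5.19, 5.16 and 5.10 on the log2 scale on activated replicates 1, 2 and 3. The step could therefore hardly have changed the lists, and it does not decide on scaling of the array. A few NK and dendritic cells in this CD4+ GB113+ sort of at least 95% purity are a candidate source, with Gzma at 2489.5, H2-Aa at 1174.6 and Cd74 at 1096.4, and this stays open. Expression by the T cells themselves stays open too. Of the 50 members, 11 are also on any of the 25 gene lists. Those lists include chemokine, adhesion and interferon genes that other cells express, so this overlap does not decide it. Of the 22 members higher by more than 1, against 1 of the 44 on the other 4 lists, 16 are on none of the gene lists. The median difference over all members on none was 0.78.

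The lower interferon-response genes beside a higher Ifng are the second pattern weighed. The split of the arrays by bioC has arrays of both groups on each side, so it could hardly make a difference between the groups. The type I list's median log2 fold change nearer to 0 within either side of the split was -1.05. Every called gene has groups that do not overlap, which fixed its sign on each side beforehand, so this value adds little. A batch that follows another split was not tested. A single naive array as the cause is argued against, because the median nearer to 0 without either naive array was -1.09. After quantile normalization the median was -1.03. That step moved the median of all tested genes only from -0.032 to -0.027, since the arrays were already scaled alike. It could hardly have changed the list, so it does not decide on array scaling. Differences in interferon exposure between the pools of mice, in handling between experiments, or between T cell states may underlie the pattern; none of these was tested, and each goes with the groups.

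Dntt, Ccr9 and Cd8b1, genes also known from developing T cells, were lower in activated cells, and a hypothesis is that the naive samples hold thymocyte-stage transcripts. The 11 tested thymocyte-associated genes whose values had not been looked at had a median log2 fold change of 0.017, at percentile 63.4 of 10000 lists of the same size matched on mean expression, and 2 of them, Sox4 and Cd24a, rose. The bound set beforehand against the hypothesis was met, but it was wrongly chosen: the members go both ways, 6 positive and 5 negative, and 5 of the 11 had a mean intensity over 100, with a median of -0.03. Rag1 and Rag2, also on the thymocyte list, did not pass the filter. Their intensities on naive replicates 1 and 2 were 0.9 and 0.4 for Rag1 and 1.1 and 1.6 for Rag2. Ptcra lay at 20.8 and 3.0 there, with a log2 fold change of 0.02. These genes gave no sign of thymocyte-stage transcripts, but values this dim decide little. A median near 0 over the tested members decides nothing, and the hypothesis stays open.

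The rise of Egr2, Egr3, Nr4a1, Izumo1r and Lag3, genes described in unresponsive CD4+ T cells, gave the hypothesis of an anergy-associated program. The 12 tested members of an anergy list whose values had not been looked at had a median of 0.17, at percentile 93.0 of the matched lists, below the 95th that was required; the 10 of them with a mean intensity over 100 had a median of 0.39. Dtx1, Ndfip1 and Dgkz rose by 0.96, 0.90 and 0.68, and the diacylglycerol kinase Dgka and the corepressor Tle4 fell by 0.88 and 0.57. The test leaves the hypothesis open. Egr2, Egr3 and Nr4a1 are also induced by recent receptor signalling.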
